A study of Homo sapiens with 27 samples.

How the data were processed

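The series holds polyA RNA-seq libraries from mucosal biopsies of the human esophagus, 27 in all. Per the labels, 7 came from healthy controls, 11 from eosinophilic esophagitis (EoE) without fibrostenosis (non-FS EoE) and 9 from fibrostenotic EoE (FS EoE). EoE is a chronic inflammation of the esophagus in which eosinophils enter the squamous epithelium, and fibrostenosis is narrowing of the esophagus with scarring. Total RNA was isolated with a Qiagen RNeasy Mini kit and libraries were made with a strand-specific Illumina TruSeq poly(A) kit, per the labels' protocols. The labels give no batch, no pairing and no statement that each library is a separate donor. The codes in the labels differ for every library, so each was treated as a separate sample, and p-values measure the spread between these samples.

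The authors deposited a table of raw read counts per gene. A second set of columns holds RPKM values made by the authors, which scale each count by gene length and by the total of counted reads. Recomputing RPKM from the deposited counts, lengths and column totals matched 100% of values within a tolerance of 0.01%, so the RPKM carries a scaling to total counts only. Gene start, end and length are other columns of the deposited table, and coordinates are given as in that table, on the human build hg19 (GRCh37). The submitters' processing notes name bcl2fastq, FastQC 0.11.5, TopHat2 2.0.13, Bowtie2 2.2.3.0, SAMtools 1.3.1, Picard 1.129 and HTSeq 0.6.1, without their roles. The strand setting of the counting and the gene annotation release are not given in the sources used here. Genes that overlap on opposite strands, and near-identical copies such as TPSAB1 with TPSB2 and SERPINB4 with SERPINB3, are therefore uncertain as single genes. The table lists 597 entries at several loci, and genes such as TAP1, PSMB8, C2, MUC22, MAPT and TNF have no single position.

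The table holds 25369 genes. Genes on Y alone, XIST and TSIX were left out of all tests (108 entries), leaving 25261. Symbols of 28 entries read as dates, and 2 symbols were listed more than once. Column totals ran from 26151026 to 38744420 counts. No difference of totals between groups passed an exact permutation test (adjusted p = 0.989 for each comparison). All 351 pairs of libraries differed by more than sampling noise (lowest chi-square per gene 42.97), so every library was counted once. Intervals cover the spread between libraries, not technical steps that were shared by them.

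Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 with TMM scaling. Genes passed a filter on low counts, which left 15533. It asked for at least 10 counts at the median depth in as many libraries, of any group, as the smallest group holds. At least 15 counts in total were also needed. A gene could therefore pass with few counts in controls. A single fit held all 27 libraries with a term per group, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Values of log2 fold change are given with approximate standard errors (SE). Each SE is the size of the log2 fold change divided by the square root of its F statistic. It was not estimated separately by the fit and restates the p-value, and the intervals of fold changes were built from it. It is unreliable where control counts are very low or the fold change is very small. CPM values are counts scaled to a common library size with the TMM factors, with standard deviations (SD). Log2-CPM values used a prior count of 2.

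The groups, tests, gene lists, processing alternatives and rule for named genes were fixed before the data were examined. There were 39 gene lists of cell type markers and pathways, with 833 distinct genes, of which 832 were matched to the table, 10 of them by an older symbol. Lists with at least 5 measured genes, 38 in all, were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Camera compares a list with the other genes. The directional p of fry tests whether the genes of a list move, on balance, in a single direction, and its mixed p tests whether they change in either direction, and neither compares the list with other genes. The erythrocyte list had fewer than 5 measured genes and was not tested. The rule for named genes took, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2-CPM of at least 2, up to 4 members of each list with the smallest p, and 30 fixed genes, of which 29 were measured (IL5 was not). If fewer than 10 passed between the EoE groups, those that passed at any mean level were to be named by smallest p. No gene passed there, so this step named none. AFF3 lies outside that rule and was chosen after its values were seen. The 132 genes recomputed under each alternative come from that rule, except AFF3.

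The same steps were tested on simulated counts for the real genes, means and library sizes with 200 genes changed. For non-FS EoE against control (15405 genes), edgeR recovered 71 of 100 genes changed 2-fold and 91 of 100 changed 4-fold, and 3.93% of its calls were false. For FS EoE against control (15410 genes) it recovered 73 and 95 of 100, with 6.81% false calls. For FS against non-FS EoE (15406 genes) it recovered 74 and 97 of 100, with 2.65% false calls, while DESeq2 gave 11.6% false calls. In the same simulations the cell cycle list was the only list raised, by 1.5-fold, and each list test found it and called 0 other lists. Genes were drawn independently throughout, so that count does not measure false list calls among correlated genes. For the same reason the shares recovered and false do not measure those among correlated genes. Recovery where few genes differ was not measured either, since 200 changed genes were planted.

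List scores for relations between EoE libraries were means of log2-CPM centred per gene over the 20 EoE libraries. Pearson and Spearman correlations had permutation p-values, exact in FS EoE and from 1e+05 resamples otherwise, adjusted over 18 relations. The 2 comparisons with control share the same 7 control libraries, so 20 simulated pairs of unchanged groups against those controls, the overlap of independent lists, and 35 splits of the controls into separate parts of 3 and 4 were computed beside the observed overlap. Other groupings of the libraries were refitted with 100 splits per comparison, the real split included.

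The other settings fixed beforehand were DESeq2 size factors, upper-quartile scaling, no filter or a filter of 1 CPM in 7 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, only the compared groups in the fit, an adjusted p under 0.1, a tested fold of 1.5, 2 surrogate variables from sva 3.50.0, limma on log2(RPKM + 0.1) or log2(RPKM + 1), camera with an estimated correlation, fry, and each library left out in turn. Added after seeing the data were a smooth muscle score and an immediate early gene score as covariates, and a fit without the 3 libraries richest in smooth muscle transcripts (control replicates 1 and 2 and non-FS EoE replicate 5). Tables, permutation tests and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The values of 1 gene are not reported here.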

Results

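Esophageal mucosal biopsies were profiled by polyA RNA-seq in 7 healthy controls, 11 samples of non-FS EoE and 9 samples of FS EoE. Counted reads per library ran from 29973928 to 33277556 in controls, from 27466236 to 35714057 in non-FS EoE and from 26151026 to 38744420 in FS EoE. KRT13, a keratin of differentiated squamous epithelium, had the most counts in every library. The 10 genes with the most counts took 24.8% ± 2.47 of the reads in controls (SD, n = 7), 15.9% ± 4.54 in non-FS EoE (n = 11) and 13.1% ± 2.69 in FS EoE (n = 9). Both EoE groups differed from control (exact permutation test, two-sided, adjusted p = 0.00113 for each), and the EoE groups did not pass the test against each other (exact permutation adjusted p = 0.267). The comparisons follow the series design, which sets both EoE groups against controls.

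The first principal component of the 1000 most variable genes held 53.2% of the variance. Controls scored from -58.5 to -41.3 on it, FS EoE from -2.45 to 45.2, and non-FS EoE from -40.2 to 51.2, so that the non-FS libraries reached from the edge of the controls past the FS libraries.

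**Figure D1:**
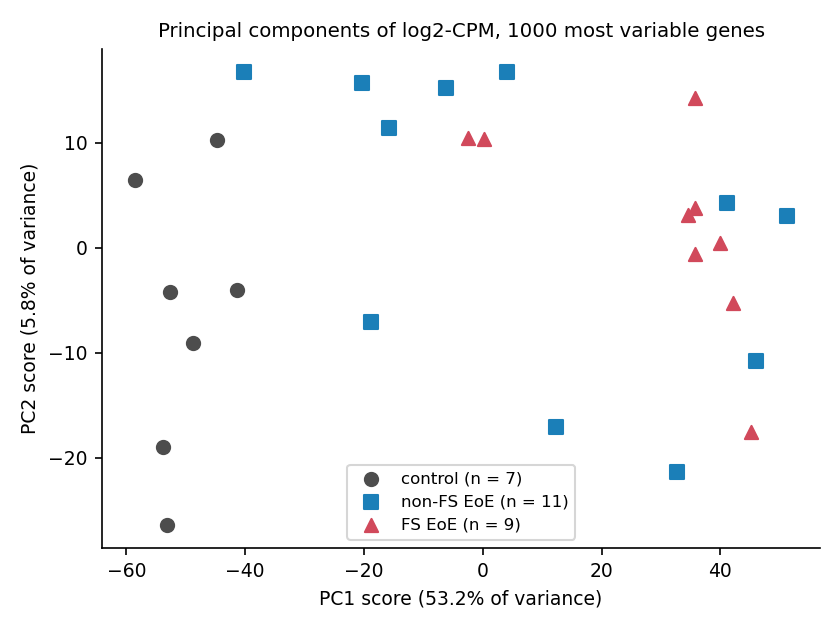
Scores of the 27 libraries on principal components 1 (53.2% of variance) and 2 (5.78%) of log2-CPM, each point a library and each marker a group. The 7 controls lie at or below -41.3 on component 1 and the 9 FS EoE libraries at or above -2.45, with non-FS EoE spread between -40.2 and 51.2.

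Non-FS EoE was compared with control to find transcripts that differ in EoE without fibrostenosis. CCL26, the eotaxin that draws eosinophils (chromosome 7, 75398842 to 75419064), rose by a log2 fold change of 7.13 ± 0.95 (SE, adjusted p = 3.33e-05), from 1.12 ± 1.06 CPM (SD, n = 7) to 157 ± 162 CPM (SD, n = 11). It was above all controls in 11 of 11 libraries. ALOX15, a lipoxygenase (chromosome 17, 4534214 to 4544960), rose by 9.48 ± 1.21, and CPA3, the mast cell carboxypeptidase (chromosome 3, 148583043 to 148614872), rose by 4.62 ± 0.75. DSG1, a desmosomal cadherin of the upper epithelium (chromosome 18, 28898052 to 28937393), fell by 2.89 ± 0.45, from 65.8 ± 27.7 CPM (n = 7) to 8.89 ± 8.49 CPM (n = 11), below all controls in 11 of 11 libraries. KRT13 (chromosome 17, 39657233 to 39661865) fell by 0.90 ± 0.24.

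Among the 20 measured IL-13-induced esophageal epithelial genes, 16 rose, 1 fell and 3 did not pass the test, and adjusted over the list alone 17 rose and 2 fell. CDH26, a cadherin, rose by 4.01 ± 0.56 (adjusted p = 6.19e-05), CAPN14, a calpain protease of the esophageal epithelium, by 1.59 ± 0.30 (0.000818), SERPINB4 by 2.83 ± 0.45, and ANO1, a chloride channel, by 3.72 ± 0.42. Camera called the list higher (adjusted p = 1.58e-11), with adjusted p = 0.264 with an estimated correlation. The 13 measured type 2 cytokines and receptors had 7 higher and 6 not called (8 higher and 1 lower adjusted over the list alone). Camera gave adjusted p = 0.000315, and 0.264 with an estimated correlation. IL1RL1, the IL-33 receptor, rose by 3.43 ± 0.62 and IL17RB by 2.72 ± 0.48. TSLP, an epithelial cytokine, had 0.48 ± 0.25 and did not pass (adjusted p = 0.174). IL13 rose by 4.68 ± 0.96 (adjusted p = 0.00174), on 5 counts in the controls in all.

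Mast cell markers rose in 14 of 15 measured genes, with 1 not called (14 higher and 1 lower adjusted over the list alone). Adjusted p by camera was 3.91e-11, and 0.264 with an estimated correlation. MS4A2, the beta chain of the IgE receptor, rose by 3.97 ± 0.66, HDC, which makes histamine, by 4.54 ± 0.78, and the tryptase TPSAB1 by 4.15 ± 0.72. Eosinophil markers had 9 of 13 higher and 4 not called (10 higher adjusted over the list alone). Camera gave adjusted p = 1.77e-07, and 0.264 with an estimated correlation. CLC, the Charcot-Leyden crystal protein, rose by 6.32 ± 0.85, with 5 counts over the 7 controls and 913 over the 11 non-FS libraries, and IL5RA rose by 3.39 ± 0.65. Macrophage and monocyte markers had 5 of 18 higher and 1 lower (9 and 1 adjusted over the list alone). Adjusted p by camera was 0.0124, and 0.615 with an estimated correlation. Among other cell types, T cell markers had 0 of 17 called, cytotoxic lymphocyte markers 1 of 15 higher, regulatory and activated T cell markers 1 of 11 higher, B cell and plasma cell markers 5 of 10 higher, dendritic and Langerhans cell markers 2 of 15 lower, and neutrophil markers 2 of 6 lower. Camera called none of these 6 lists (adjusted p from 0.0712 to 0.226).

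Type I interferon-stimulated genes rose in 22 of 35 members with 13 not called (31 higher adjusted over the list alone; camera adjusted p = 1.12e-09, and 0.580 with an estimated correlation), among them IFI35 by 2.71 ± 0.42, the RNA sensor DDX58 by 1.47 ± 0.22 and IFI27 by 2.62 ± 0.53. Interferon-gamma response and antigen presentation genes rose in 11 of 26 members (11 higher and 3 lower adjusted over the list alone). Camera gave adjusted p = 0.0409, and 0.728 with an estimated correlation. The proteasome subunit PSMB10 rose by 1.21 ± 0.24. Cell cycle genes rose in 19 of 30 (24 adjusted over the list alone; camera adjusted p = 5.37e-08, and 0.580 with an estimated correlation), including the mitotic kinase AURKA by 0.94 ± 0.23 and RRM2, a subunit of ribonucleotide reductase, by 0.95 ± 0.22. Oxidative phosphorylation genes rose in 12 of 32 (18 adjusted over the list alone; camera adjusted p = 1.15e-05, and 0.615 with an estimated correlation), UQCRC1 by 0.37 ± 0.10.

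Differentiated squamous markers fell in 12 of 32 members, rose in 1 and were not called in 19 (20 lower and 1 higher adjusted over the list alone). Adjusted p by camera was 9.82e-09, and 0.580 with an estimated correlation. Involucrin, IVL, fell by 1.15 ± 0.28, the small proline-rich protein SPRR3 by 1.21 ± 0.36, and KRT4 by 1.17 ± 0.35. Repetin, RPTN, rose by 3.11 ± 0.62. Epidermal differentiation complex genes had 6 of 25 lower and 2 higher (13 and 2 adjusted over the list alone). Camera gave adjusted p = 0.000308, and 0.585 with an estimated correlation. Junction genes of desmosomes, tight and adherens junctions had 6 of 26 lower and 2 higher (7 and 2 adjusted over the list alone). Adjusted p by camera was 0.0409, and 0.615 with an estimated correlation. The desmosomal plakophilin PKP2 rose by 2.05 ± 0.26. Basal squamous markers had 4 of 19 higher and 1 lower, and camera did not call them (adjusted p = 0.895). Mucins and epithelial ion transport genes rose in 7 of 23 (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0409, and 0.530 with an estimated correlation), SLC9A3, a sodium-proton exchanger, by 3.25 ± 0.39. Glycolysis and hypoxia response genes fell in 8 of 25 and rose in 1 (9 and 2 adjusted over the list alone). Camera gave adjusted p = 0.00248, and 0.580 with an estimated correlation.

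Matrix crosslinking and remodelling genes had 7 of 26 higher and 1 lower (9 and 2 adjusted over the list alone), not called by camera (adjusted p = 0.0712). LOXL4, a lysyl oxidase, rose by 3.76 ± 0.59 and the inhibitor TIMP1 by 1.92 ± 0.45. Collagens and matrix proteins had 1 of 25 higher and 2 lower (camera adjusted p = 0.0717), with COL1A1 at 0.38 ± 0.28 (adjusted p = 0.343) and POSTN, periostin, up by 6.99 ± 1.18. Fibroblast markers had 1 of 13 higher and 2 lower (camera adjusted p = 0.211), and endothelial markers 1 of 19 higher (0.183). TGF-beta pathway and targets had 5 of 27 higher and 1 lower (0.925), with TGFB1 at -0.02 ± 0.25. Smooth muscle markers had 1 of 14 lower (1 adjusted over the list alone; camera adjusted p = 0.0409, and 0.728 with an estimated correlation), and MYH11, smooth muscle myosin, had -1.70 ± 1.06 (adjusted p = 0.263).

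Of the 15533 genes tested in non-FS EoE against control, 1859 were higher and 1264 lower by edgeR, 588 and 385 of them by at least 2-fold. RPKM, scaled to total counts and tested with limma, gave 6500 higher and 729 lower, and shifted the median of all genes by 0.30, against 0.01 with TMM. The lower count was 820 without control replicate 3, and without the 3 libraries richest in smooth muscle transcripts, chosen after seeing the data, the counts were 878 and 393, and KRT4, KRT13, SPRR3 and AURKA did not pass. With 2 surrogate variables as covariates 315 genes were higher and 137 lower, and of the genes named above IL13, IL17RB, KRT4, KRT13, SPRR3, IVL, IFI27, AURKA, RRM2, PSMB10 and TIMP1 did not pass, and POSTN did not pass with limma-voom.

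**Figure D2:**
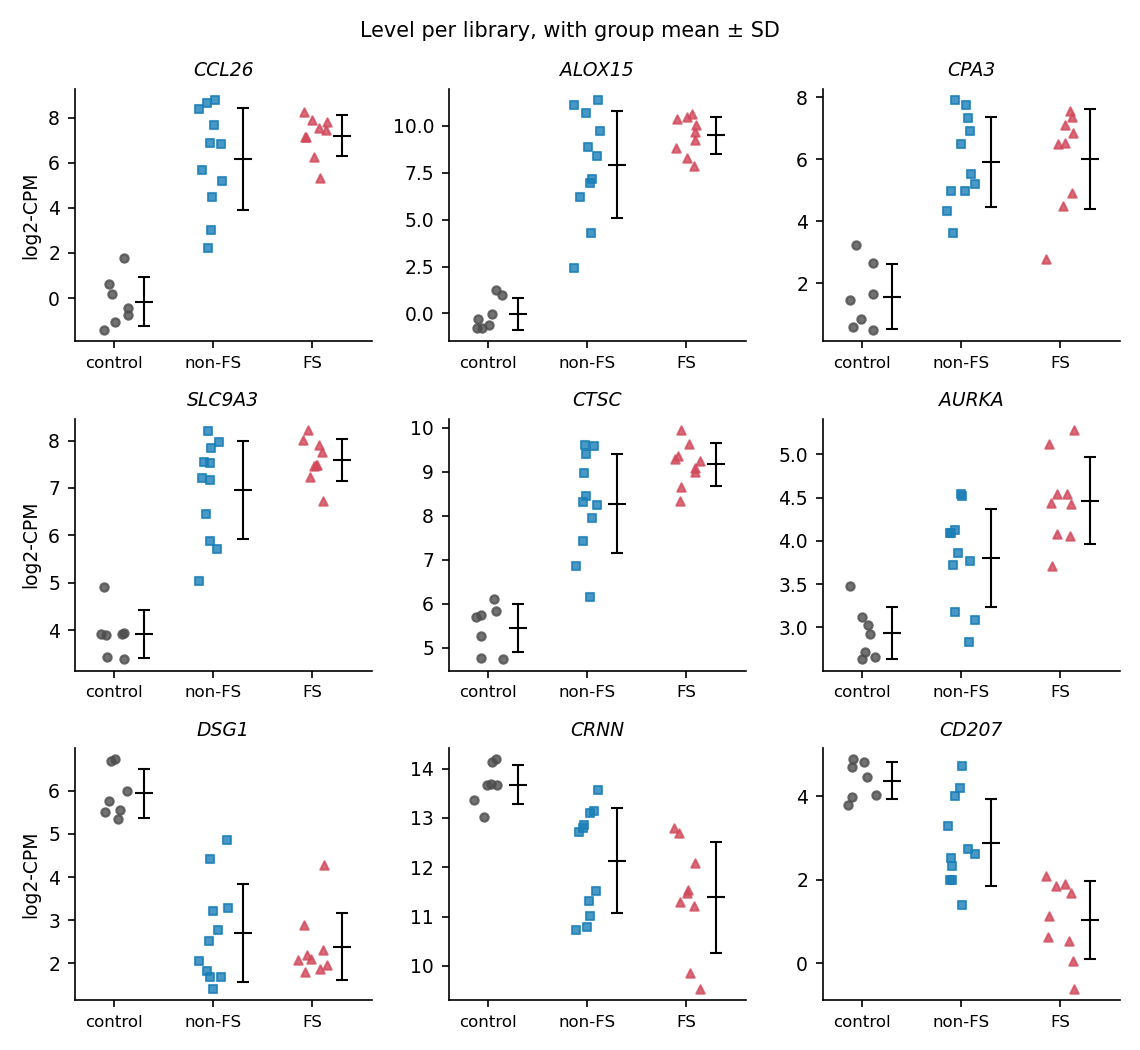
Log2-CPM of 9 genes in each library (points) with group mean ± SD, for control (n = 7), non-FS EoE (n = 11) and FS EoE (n = 9). CCL26, ALOX15, SLC9A3 and CTSC lie above all controls in 11 of 11 non-FS and 9 of 9 FS libraries, and DSG1 lies below all controls in the same libraries.

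FS EoE was compared with control to find transcripts that differ in EoE with fibrostenosis. CCL26 rose by a log2 fold change of 7.25 ± 0.96 (SE, adjusted p = 9.59e-06), to 170 ± 80.8 CPM (SD, n = 9) from 1.12 ± 1.06 CPM (n = 7), and ALOX15 rose by 9.66 ± 1.22. CTSC, the lysosomal protease cathepsin C (chromosome 11, 88026760 to 88070941), rose by 3.71 ± 0.43 and PRRX1, a mesenchymal transcription factor (chromosome 1, 170633313 to 170708541), by 4.23 ± 0.48. CD207, langerin of Langerhans cells (chromosome 2, 71057343 to 71062953), fell by 3.20 ± 0.45, from 21.6 ± 6.42 CPM (n = 7) to 2.34 ± 1.32 CPM (n = 9), below all controls in 9 of 9 libraries. DSG1 fell by 3.42 ± 0.50 and the small proline-rich protein SPRR3 by 1.77 ± 0.38.

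IL-13-induced genes had 17 of 20 higher and 3 lower, the same counts adjusted over the list alone (camera adjusted p = 6.77e-10, and 0.527 with an estimated correlation). CDH26 rose by 4.11 ± 0.57 and TNFAIP6, a hyaluronan-binding protein, by 10.25 ± 1.70 on 24 counts in the controls. Type 2 cytokines and receptors had 8 of 13 higher and 1 lower, also over the list alone (camera adjusted p = 0.00156, and 0.527 with an estimated correlation), and TSLP had 0.52 ± 0.26 (adjusted p = 0.117). Mast cell markers rose in 14 of 15 and fell in 1, also over the list alone (camera adjusted p = 1.26e-06, and 0.527 with an estimated correlation), CPA3 by 4.67 ± 0.76 and MS4A2 by 3.85 ± 0.66. Eosinophil markers rose in 9 of 13 (10 adjusted over the list alone). Adjusted p by camera was 1.97e-05, and 0.527 with an estimated correlation. CLC rose by 7.15 ± 0.86. B cell and plasma cell markers rose in 6 of 10, also over the list alone (camera adjusted p = 0.0198, and 0.626 with an estimated correlation). IGJ, the immunoglobulin joining chain, rose by 4.52 ± 0.91.

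Dendritic and Langerhans cell markers fell in 6 of 15, also over the list alone (camera adjusted p = 0.0224, and 0.626 with an estimated correlation). CD1A, a lipid-presenting molecule, fell by 1.92 ± 0.42, the chemokine CCL17 by 1.71 ± 0.37 and XCR1 by 2.11 ± 0.57. Macrophage and monocyte markers had 9 of 18 higher and 1 lower (camera adjusted p = 0.0804), neutrophil markers 2 of 6 lower (0.151), T cell markers 0 of 17 called (0.653), cytotoxic lymphocyte markers 0 of 15 (0.576), and regulatory and activated T cell markers 2 of 11 higher (0.124). Skeletal muscle markers had 2 of 5 lower (0.111) here and 1 of 5 lower (0.174) in non-FS EoE.

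Cell cycle genes rose in 29 of 30 (30 adjusted over the list alone; camera adjusted p = 2.07e-12, and 0.527 with an estimated correlation), AURKA by 1.58 ± 0.25 and RRM2 by 1.40 ± 0.23. Type I interferon-stimulated genes rose in 22 of 35 (25 adjusted over the list alone; camera adjusted p = 1.26e-06, and 0.626 with an estimated correlation), and interferon-gamma response genes in 13 of 26, also over the list alone (camera adjusted p = 0.00665, and 0.713 with an estimated correlation). Oxidative phosphorylation genes rose in 22 of 32 (23 adjusted over the list alone; camera adjusted p = 8.49e-06, and 0.626 with an estimated correlation), UQCRC1 by 0.56 ± 0.10. Complement genes rose in 7 of 18, also over the list alone (camera adjusted p = 0.0199, and 0.607 with an estimated correlation), CFI by 2.89 ± 0.40 and C2 by 2.33 ± 0.31. In non-FS EoE 6 of 18 rose and camera did not call them (adjusted p = 0.0717). Fry called complement genes in both groups (directional adjusted p = 0.0332 in non-FS and 0.000565 in FS EoE).

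Differentiated squamous markers fell in 25 of 32 and rose in 1 (28 and 1 adjusted over the list alone; camera adjusted p = 5.62e-09, and 0.527 with an estimated correlation), with KRT13 down by 1.29 ± 0.25 and the envelope protein EVPL down by 0.89 ± 0.18. Epidermal differentiation complex genes had 12 of 25 lower and 2 higher (13 and 2 adjusted over the list alone). Camera gave adjusted p = 0.00311, and 0.626 with an estimated correlation. Filaggrin, FLG, fell by 3.16 ± 0.97 and RPTN rose by 3.30 ± 0.63. Junction genes had 10 of 26 lower and 3 higher (11 and 3 adjusted over the list alone; camera adjusted p = 0.0241, and 0.626 with an estimated correlation), with DSC1 down by 2.45 ± 0.37. Epithelial protease inhibitors had 10 of 25 lower and 7 higher (camera adjusted p = 0.563), SPINK5 down by 1.43 ± 0.26 and SPINK7 by 2.52 ± 0.80. In non-FS EoE there were 6 lower and 5 higher (0.689). Epithelial proteases had 8 of 30 higher and 8 lower (0.972), and in non-FS EoE 6 higher (0.971). Basal squamous markers had 4 of 19 higher and 2 lower (0.504). CDH3 rose by 2.46 ± 0.39. Mucins and ion transport genes had 8 of 23 higher and 7 lower (0.504), SLC9A3 up by 3.66 ± 0.40 and CFTR down by 1.42 ± 0.45. Glycolysis and hypoxia genes had 9 of 25 lower and 2 higher (10 and 2 adjusted over the list alone). Adjusted p by camera was 0.0258, and 0.626 with an estimated correlation.

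Matrix crosslinking and remodelling genes rose in 13 of 26 and fell in 4 (15 and 4 adjusted over the list alone; camera adjusted p = 0.00334, and 0.527 with an estimated correlation), LOXL4 by 4.50 ± 0.61, LOX by 2.70 ± 0.48 and TIMP1 by 2.25 ± 0.47. Collagens and matrix proteins had 3 of 25 higher and 4 lower (camera adjusted p = 0.994). COL1A1 rose by 1.07 ± 0.29 and elastin, ELN, fell by 2.04 ± 0.35. Fibroblast markers had 5 of 13 higher and 4 lower (0.972), endothelial markers 2 of 19 higher and 4 lower (0.507), and epithelial-mesenchymal transition genes 3 of 12 higher and 1 lower (0.151), against 1 higher (0.468) in non-FS EoE. TGF-beta pathway and targets had 6 of 27 higher and 4 lower (0.504), and TGFB1 had -0.19 ± 0.26. Smooth muscle markers fell in 8 of 14, also over the list alone (camera adjusted p = 0.0312, and 0.732 with an estimated correlation). MYH11 fell by 4.90 ± 1.28, from 54.2 ± 93.7 CPM (SD, n = 7) to 1.79 ± 2.23 CPM (n = 9), with control replicates 1 and 2 having smooth muscle scores of 2.89 and 4.04 against 1.38 or less in the other controls. MYH11 did not pass with limma-voom (adjusted p = 0.0785), nor without the 3 libraries richest in smooth muscle transcripts (-2.08, adjusted p = 0.112). FN1, fibronectin, fell by 2.36 ± 0.87 (adjusted p = 0.0330) and lost the call without control replicate 1 (0.0597), control replicate 2 (0.242), and FS EoE replicates 2 (0.0553), 6 (0.0546) and 8 (0.0529).

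Of the 15533 genes tested in FS EoE against control, 3150 were higher and 2814 lower by edgeR, 975 and 1059 of them by at least 2-fold. RPKM gave 8101 higher and 1222 lower and shifted the median of all genes by 0.38. Without the 3 libraries richest in smooth muscle transcripts 4872 genes were called, 4643 of them shared with the 5964 above. With 2 surrogate variables 810 were higher and 459 lower, and IGJ, CD1A, CCL17, XCR1, SPRR3, KRT13, EVPL, FLG, SPINK7, CFTR, TIMP1, COL1A1 and FN1 did not pass, nor did TNFAIP6 with limma-voom.

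**Figure D3:**
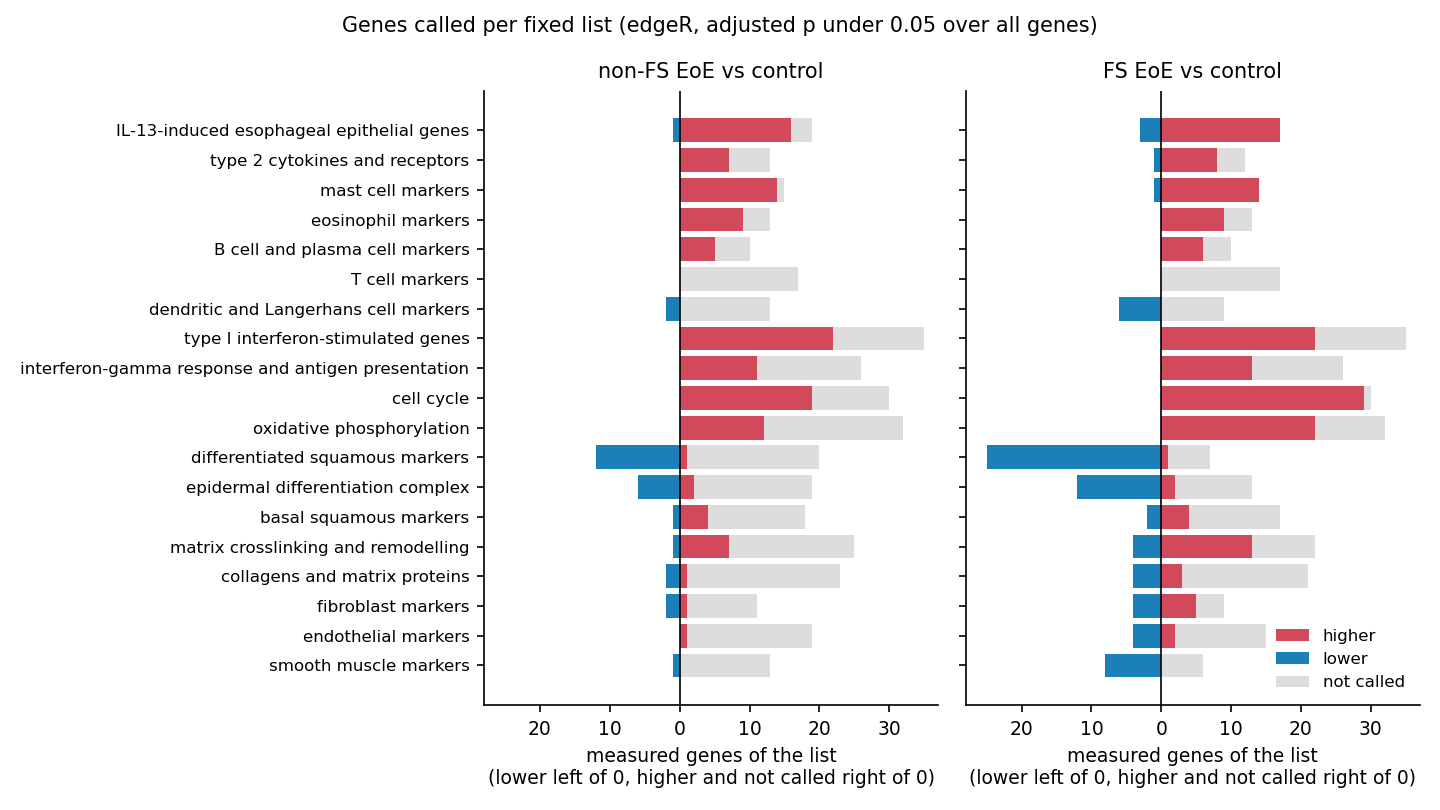
Number of measured genes called higher (right of 0), lower (left of 0) and not called (grey) for 19 fixed lists in each EoE group against control, by edgeR over all genes. Cell cycle genes had 19 of 30 higher in non-FS EoE and 29 of 30 in FS EoE, and differentiated squamous markers had 12 and 25 of 32 lower. Over all 15533 genes 20.1% and 38.4% were called. Between the EoE groups edgeR called 0 of 30 and 0 of 32.

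The calls of the 2 comparisons with control overlapped in 2966 genes in the same direction, 1789 higher and 1177 lower, and 0 in opposite directions, where independent lists would share 377 and 229. The log2 fold changes had r = 0.931 across genes, which are not independent replicates, and a covariance of 0.579. Unchanged groups simulated against the same controls had a median of 0 calls each (highest 2 and 1). With almost no calls to share, their shared count (median 0, highest 1) does not measure what the shared controls add to the overlap. Their log2 fold changes had r = 0.609 and a covariance of 0.0494. Genes were drawn independently in these simulations, so they lack the correlation between genes of the real libraries and do not measure its effect on the overlap. With the controls split into separate parts, a median of 826 genes were shared (270 to 1253), with r = 0.811 and a covariance of 0.552.

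FS EoE was compared with non-FS EoE to ask which transcripts differ between the groups with and without fibrostenosis. No gene passed the edgeR test among 15533, while 1780 had an unadjusted p under 0.05. DESeq2 called 61 genes, 17 higher and 44 lower, limma-voom called 0, and 1 passed when only the compared groups were fitted. CD207 was closest among the genes named by rule, with a log2 fold change of -2.01 ± 0.41 (SE, adjusted p = 0.116), at 9.45 ± 7.58 CPM in non-FS EoE (SD, n = 11) and 2.34 ± 1.32 CPM in FS EoE (n = 9). AFF3, chosen after its values were seen, had -2.92 ± 0.52 (adjusted p = 0.101), and passed without non-FS EoE replicate 2 (0.0219), 3 (0.00992) or 5 (0.0236). Without those replicates 1, 4 and 4 genes passed in all.

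Beneath the threshold, PRRX1 had 1.27 ± 0.35 (adjusted p = 0.218), AURKA 0.65 ± 0.21 (0.281) and COL1A1 0.68 ± 0.25 (0.322). CCL26 had 0.12 ± 0.60, with a 95% interval of -1.12 to 1.35, POSTN 0.30 ± 0.76 and CPA3 0.05 ± 0.55. TGFB1 had -0.17 ± 0.23. Genes passing with DESeq2 included CD207, MUC22, MAPT and AFF3.

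**Figure D4:**
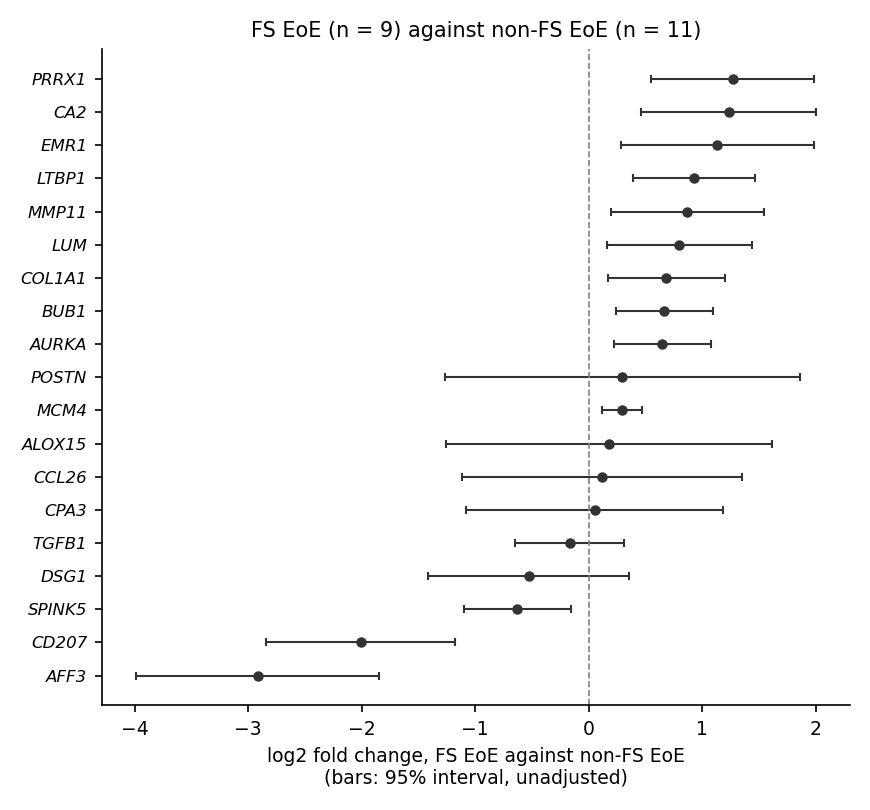
Log2 fold change of 19 genes in FS EoE (n = 9) against non-FS EoE (n = 11), points with unadjusted 95% intervals. No gene passed after adjustment by edgeR (61 did by DESeq2, CD207 among them), and the intervals of CCL26 (-1.12 to 1.35) and CPA3 include 0 while that of CD207 lies below it.

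Camera with the preset correlation called 12 lists between the EoE groups, 15 in non-FS EoE against control and 17 in FS EoE against control. With an estimated correlation 0 of these calls held. The directional p of fry, which does not compare a list with other genes, called 15 lists in non-FS EoE and 20 in FS EoE against control. Its adjusted p was 5.09e-06 and 1.59e-07 for IL-13-induced genes, and 0.00013 and 0.000244 for mast cell markers, in non-FS and FS EoE. Between the EoE groups it called 0 lists. Cell cycle genes were higher in FS EoE (median 0.44, 0 of 30 genes called over all genes by edgeR, as for each gene count here, and 20 adjusted over the list alone; adjusted p = 3.68e-16, and 0.613 with an estimated correlation), and fry did not call the list (directional adjusted p = 0.240). Immediate early genes had a median of 0.55 (0 of 19 called; adjusted p = 3.72e-07, and 0.613 with an estimated correlation), matrix crosslinking genes 0.35 (0 of 26; 0.000248, and 0.613), IL-13-induced genes 0.26 (0 of 20; 0.000304, and 0.613), and collagens and matrix proteins 0.27 (0 of 25; 0.00164, and 0.781). Differentiated squamous markers had a median of -0.51 (0 of 32; 9.19e-05, and 0.781) and dendritic and Langerhans cell markers -0.19 (0 of 15 by edgeR, while CD207 passed with DESeq2, and 1 lower adjusted over the list alone; 0.0117, and 0.690). The other called lists were interferon-gamma response genes (0.00262, and 0.786), oxidative phosphorylation (0.00627, and 0.786), complement (0.0128, and 0.613), B cell and plasma cell markers (0.0148, and 0.781) and epithelial-mesenchymal transition (0.0235, and 0.613), each higher in FS EoE, with the second p in each bracket from an estimated correlation. Smooth muscle markers had 7 of 14 lower adjusted over the list alone and 0 over all genes, and camera did not call them (adjusted p = 0.187). The 26 lists that camera did not call had adjusted p-values from 0.0633, for TGF-beta pathway and targets, to 0.860, for epithelial proteases. The TGF-beta list had 4 higher and 1 lower adjusted over the list alone, and the mixed adjusted p of fry was 0.0106, while its directional adjusted p was 0.240.

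Among the 20 EoE libraries, the eosinophil marker score rose with the mast cell marker score (Pearson r = 0.656, permutation p = 0.00184, adjusted over 18 relations 0.00828; Spearman rho = 0.680, adjusted 0.00545), and r was 0.680 without the 2 libraries farthest from the median. It followed the IL-13-induced genes (r = 0.722, permutation p = 0.00012, adjusted 0.00108; rho = 0.791) and ran against differentiated squamous markers (r = -0.598, permutation p = 0.00582, adjusted 0.0175; rho = -0.606). For type I interferon-stimulated genes r was 0.534 (permutation p = 0.0161, adjusted 0.0363), with rho = 0.477 (adjusted 0.0688). Matrix crosslinking genes (r = 0.288, adjusted permutation p = 0.345) and cell cycle genes (r = 0.160, adjusted permutation p = 0.533) did not pass.

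Within non-FS EoE (n = 11) the mast cell relation had r = 0.956 (permutation p = 2e-05, adjusted 0.00036; rho = 0.982), 0.941 without the 2 farthest libraries, and IL-13-induced genes had r = 0.821 (permutation p = 0.00175, adjusted 0.00828; rho = 0.909). Squamous markers had r = -0.810 (permutation p = 0.00477, adjusted 0.0172; rho = -0.746) and interferon-stimulated genes r = 0.698 (permutation p = 0.0212, adjusted 0.0423; rho = 0.736). Within FS EoE (n = 9) the mast cell relation had r = 0.345 (exact permutation p = 0.363; rho = 0.283) and did not pass. IL-13-induced genes had r = 0.791 (exact permutation p = 0.0109, adjusted 0.0281; rho = 0.733, adjusted 0.0688), which dropped to 0.492 without the 2 farthest libraries and so rested on them. The other 6 relations within the groups did not pass, and the labels give no batch within which to repeat them. No relation was adjusted for the first principal component, on which non-FS libraries ran from -40.2 to 51.2 and FS libraries from -2.45 to 45.2. Whether the relations are particular to these lists, beyond that spread, was not tested.

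**Figure D5:**
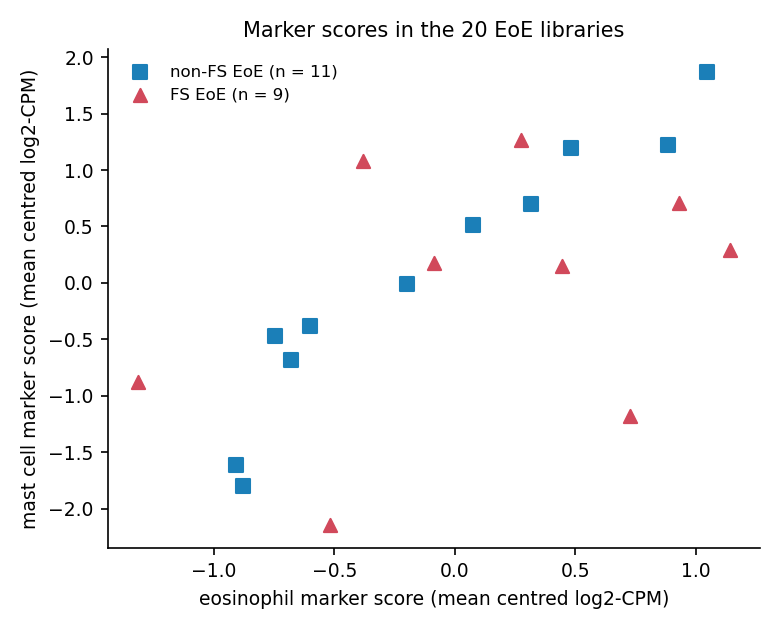
Mast cell marker score against eosinophil marker score (mean centred log2-CPM) in the 20 EoE libraries, each point a library. The 11 non-FS libraries follow a line (r = 0.956) and the 9 FS libraries scatter (r = 0.345).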

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

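The splits of the libraries, the lowest ratio without a non-FS library, the smooth muscle and immediate early tests and the difference between relations were tests chosen after the results were seen.

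Single libraries stood far from the rest of their group in 26 values of the control (n = 7) and FS EoE (n = 9) groups, by the gap to the nearest library over the range of the group. Such a gap arises by chance in about 1 of 20 groups: 19 of 264 gene tests had one where 13.2 were expected, 7 of 76 list score tests where 3.8 were expected, and 0 of 8 other tests. The non-FS group (n = 11) was not tested this way. Control replicates 2 and 7 had 5 such values each and FS EoE replicate 5 had 4.

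Control replicate 7 was high in the IL-13-induced score (-1.76, median of the other controls -2.55), and in log2-CPM of CDH26 (6.84, others 3.21), SLC9A3 (4.91, others 3.90), IL13 (-1.98, others -4.00) and CEBPE (-3.31, others -4.00), the last 2 near the floor. Control replicate 2 was low in the epidermal differentiation complex score (-1.25, others 1.12), the epithelial protease score (-0.58, others 0.03) and SUSD2 (0.13, others 1.37), and high in NR4A1 (4.97, others 1.25) and ATF3 (5.35, others 2.27). Control replicate 6 was high in the oxidative phosphorylation score (0.16, others -0.29) and NDUFA9 (6.48, others 6.02), control replicate 4 low in BNIP3 (5.04, others 5.97), and control replicate 1 low in DSC1 (-0.42, others 0.64).

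In FS EoE, replicate 5 was high in the smooth muscle score (0.93, others -0.82), MYH11 (2.95, others 0.28), ACTG2 (1.51, others -3.47) and DES (2.6, others -4.00). Replicate 3 was high in the glycolysis and hypoxia score (0.35, others -0.14) and IVL (9.71, others 8.03), and low in PTGDR2 (-0.70, others 1.20). Replicate 6 was low in the fibroblast score (-1, others 0.29) and LOXL1 (0.83, others 2.13). DSG1 was high in replicate 4 (4.28, others 2.09), AFF3 high in replicate 9 (0.64, others -0.54), and KRT14 low in replicate 7 (4.39, others 8.69).

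The relation of eosinophil with mast cell marker scores differed between non-FS (r = 0.956) and FS EoE (r = 0.345), with an adjusted permutation p of 0.01128 over 6 relations, in a test added after both correlations were seen. That test did not adjust for the spread of the libraries on the first principal component.

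The first pattern weighed was the larger number of genes changed in FS than in non-FS EoE, each against control (5964 against 3123, a ratio of 1.91). Leaving out each non-FS library in turn gave 1.57 (without replicate 6) to 2.59. The FS count thus stayed larger without any 1 non-FS library, though the ratio fell without replicate 6. Leaving out several non-FS libraries near the controls together was not tried. Leaving out the 10 genes with the most counts gave 1.90 but barely moved either count (3141 and 5960), so that test decides nothing about a few abundant genes. Of 100 splits of the 20 EoE libraries, 16 gave a difference of counts as large in either direction as the real 2841 (highest other 4297, its sign dropped), so chance could not be excluded. Whether the FS group differs in biology stays open.

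The second pattern was the lower level of smooth muscle transcripts in FS EoE than in control (score difference -1.62, exact permutation p = 0.0311). It rested on control replicates 1 and 2: the exact permutation p was 0.0561 without replicate 1, 0.0737 without replicate 2 and 0.237 without both, with a difference of -0.63. Within groups the 14 markers had a mean pairwise correlation of 0.684, above the 0.0563 that marks the 95th percentile of 1000 random lists. Of the 37 other fixed lists 33 were above it too, though only 2 reached the value of the smooth muscle list. Passing the random lists thus leaves varying amounts of muscle tissue undecided. Less tissue of every kind below the epithelium was not excluded: the smooth muscle score minus the fibroblast and endothelial score differed with exact permutation p = 0.0358 (the latter score alone by -0.23, exact permutation p = 0.278), but with 0.263 without both controls, and 0.0723, 0.0905, 0.0577, 0.0503, 0.0575, 0.0516, 0.0609 and 0.0536 without control replicates 1, 2, 5 and 6 and FS EoE replicates 1, 4, 7 and 8 in turn. A biological change with fibrostenosis stays open and untested.

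The third pattern was the 12 lists that camera with a preset correlation shifted between FS and non-FS EoE. In adjusted p these were cell cycle (3.68e-16), immediate early genes (3.72e-07), differentiated squamous markers (9.19e-05), matrix crosslinking (0.000248), IL-13-induced genes (0.000304), collagens and matrix proteins (0.00164), interferon-gamma response (0.00262), oxidative phosphorylation (0.00627), dendritic and Langerhans cell markers (0.0117), complement (0.0128), B cell and plasma cell markers (0.0148) and epithelial-mesenchymal transition (0.0235). With an immediate early score as a covariate 10 of the other 11 lists kept their call and direction. Of 100 splits of the libraries, 54 called as many lists (real 12, highest other 23), so chance could not be excluded, and the kept calls decide nothing about handling. No gene passed the edgeR test between these groups and no list kept its call with an estimated correlation, so a difference between them was not shown and stays open.

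The same splits were made for the other counts. For genes in non-FS EoE against control 2 of 100 splits called as many, the real split included (real 3123, highest other 5198). Another grouping thus called more genes than the real one, and chance was unlikely but not excluded. In FS EoE against control only the real split reached its count (real 5964, highest other 116). Chance was unlikely there too, and 1 of 100 is the lowest share that these splits can give. For FS against non-FS EoE 100 of 100 did (real 0, highest other over 100). For lists, 42 splits of non-FS EoE and control called as many (real 15, highest other 22) and 14 splits of FS EoE and control did (real 17, highest other 21), so chance could not be excluded for the number of list calls with a preset correlation. That number does not weigh how strongly any single list moved, and fry was not run on the splits.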

How the results depend on the processing

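The smooth muscle and immediate early covariates and the fit without 3 libraries were chosen after seeing the data, and the rest were planned. With DESeq2 size factors and with upper-quartile scaling, all 132 named genes kept direction and side of the threshold in all 3 comparisons.

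FS against non-FS EoE gave 17 higher and 44 lower genes (61) with DESeq2, 1 higher with only the compared groups and with either RPKM pseudocount, and 1 lower without the 3 libraries. Genes lower in non-FS EoE against control were 2297 with voom sample weights and 1957 at adjusted p under 0.1. A tested fold of 1.5 gave 293 higher and 67 lower (360) in non-FS EoE and 700 and 678 (1378) in FS EoE, since it asks for larger changes. With 2 surrogate variables these were 315 and 137 (452), and 810 and 459 (1269). RPKM + 0.1 gave 6500 and 729 (7229), and 8101 and 1222 (9323); RPKM + 1 gave 6302 and 726 (7028), and 8029 and 1217 (9246), with limma in place of edgeR and no TMM scaling, 2 changes at once. Without the 3 libraries non-FS EoE had 878 and 393 (1271). Lists called were 0, 0 and 0 with an estimated correlation. The directional p of fry called 15 in non-FS EoE, 20 in FS EoE and 0 between the EoE groups, where its mixed p called 1. Of the camera calls with a preset correlation, fry lost 4 in non-FS EoE and 1 in FS EoE, and it added 4 in each. Among those added were matrix crosslinking in non-FS EoE (fry adjusted p = 0.0497) and mucins and ion transport in FS EoE (0.00646). The overlap was 826 with split controls, which leaves fewer controls per fit. Where no reason is given the cause was not tested.

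Reversed directions came with 2 surrogate variables for the junction list (adjusted p = 0.898), epithelial proteases (0.000514) and interferon-gamma list (0.920) in non-FS EoE, and in FS EoE for the T cell list (0.00621), cytotoxic list (0.0336) and junction list (0.924). In log2 fold change FLG had 0.30 (adjusted p = 0.839), SPINK7 0.066 (0.955) and CFTR 0.036 there, none of which passed, and FN1 in FS EoE 0.57 (0.221) with the smooth muscle covariate. The immediate early list between EoE groups had adjusted p = 0.662 with its own score as covariate, which removes it by construction.

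Leaving out each library gave 1457 to 2215 higher, 820 (without control replicate 3) to 1651 lower and 2300 to 3866 changed genes in non-FS EoE; 2841 to 3242, 2539 to 2964 and 5380 to 6206 in FS EoE; 0 to 1, 0 to 4 and 0 to 4 between them; and 12 to 21, 16 to 19 and 9 to 15 lists. The filter of 1 CPM left out IL13, IL5RA, EMR1, XCR1, CTLA4, DSC1, FAP and TNF, and some low genes had no value with only the compared groups.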

Other observations

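All tests in this part that go beyond the fixed lists were chosen after the results were seen. Eicosanoid metabolism genes had 5 of 28 higher and 8 lower in both EoE groups against control (6 and 9 adjusted over the list alone in each), with camera adjusted p-values of 0.150 in non-FS and 0.504 in FS EoE and mixed adjusted p-values from fry of 2.66e-11 and 3.44e-14. The mixed p does not compare a list with other genes. Among lists that camera also did not call, it was 3.27e-07 and 1.06e-11 for TGF-beta pathway and targets, and 0.668 and 0.228 for neutrophil markers. LTA4H, which makes leukotriene B4, rose by 1.09 ± 0.16 in non-FS EoE (SE, n = 11 against 7) and 1.37 ± 0.16 in FS EoE (n = 9 against 7), while the lipoxygenase ALOX12 fell by 2.29 ± 0.64 and 3.26 ± 0.71 and the phospholipase PLA2G4A by 0.76 ± 0.15 and 0.98 ± 0.16. IL-1, IL-17 and NF-kB response genes also went both ways, with 4 of 24 higher and 4 lower in non-FS EoE (camera adjusted p = 0.233) and 7 higher and 5 lower in FS EoE (0.763). The chemokine CXCL6 rose by 4.84 ± 0.80 and 5.64 ± 0.82, and IL18 fell by 1.83 ± 0.39 in FS EoE.

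Glucocorticoid response genes had 1 of 13 higher and 2 lower in non-FS EoE (camera adjusted p = 0.694) and 1 higher and 3 lower in FS EoE (0.972), the higher being SGK1, which rose by 2.29 ± 0.30 and 2.74 ± 0.31. Circadian clock genes had 2 of 19 higher and 1 lower (0.421), and 2 higher and 5 lower (0.504). Columnar, gastric and gland markers had 1 of 7 higher and 1 lower (0.925), and 1 higher and 2 lower (0.866). Immediate early genes had 1 of 19 lower (0.468), and 2 higher (0.114). EGLN3, an oxygen-sensing hydroxylase, rose by 1.69 ± 0.26 and 1.87 ± 0.27 while BNIP3 fell by 1.51 ± 0.39 and 2.26 ± 0.42. Medians and means differed in sign for eicosanoid metabolism in non-FS EoE (median -0.48, mean 0.03) and FS EoE (-0.30, 0.18), for the IL-1 list (-0.57, 0.19, and -0.19, 0.48), and in non-FS EoE for circadian clock (-0.04, 0.02), epithelial-mesenchymal transition (-0.02, 0.25), TGF-beta (-0.02, 0.00), columnar markers (-0.12, 0.34) and epithelial proteases (-0.09, 0.11).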
